A study of Sphingobacterium with 6 samples.

How the data were processed

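Total RNA of Sphingobacterium sp. WM1, a bacterial strain of the phylum Bacteroidota, was sequenced from cultures with no tetracycline (control, 3 libraries) and from cultures with tetracycline at 50 mg/L (3 libraries). Groups and replicate numbers were taken from the sample titles; growth phase and time of harvest are not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries were made with an Illumina TruSeq kit from TRIzol-extracted, DNase-treated RNA, per the labels' protocols.

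Expression values were deposited as TPM per library (transcript abundance corrected for length, as a share of a fixed total), and Bowtie2, RSEM and DESeq2 are named in the submitters' processing notes, without versions. The authors' mean TPM per group, fold change (a ratio), log2 fold change, p-value and adjusted p-value stand in the same deposited table. The reference genome, filters, strand setting and adjustment method are not given in the sources used here. The table held 3794 rows: 3677 annotated genes, 69 small RNA (sRNA) rows and 48 rows for transcripts outside the annotation. Of these, 75 rows, 41 of them sRNA rows, were at 0 in every library. 4 sets of rows had identical values in every library, as near-identical copies whose reads are divided would give, and their values are uncertain. Each column summed to 1000000 over all rows together, so a transcript that takes more of the total lowers every other value. TPM keeps no sequencing depth, so the depth of the libraries is unknown and no counting interval is given.

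The design fixed before the data were examined assumed counts and named a substitute for TPM, which was used. Values were transformed to log2(TPM + 1), and genes with at least 1 TPM in at least 3 libraries (3559 genes) were fitted with limma (trend and robust options) by group alone. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 changes are tetracycline minus control on the log2(TPM + 1) scale, which understates the change of low genes. The same fit was made after dividing each library by a median-ratio factor (RLE scaling, an alternative fixed in advance). These results are called scaled, and scaled changes are relative to the typical gene. An exact 0 in this table is described as listed at 0, without a fold.

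26 gene lists had been fixed by symbol and description patterns. The list of ribosomal and transfer RNAs had 1 member and was not tested. The other 25 were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, with adjustment over the 25 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, stood beside it. Patterns took in 26 list members of other function, such as chloramphenicol acetyltransferases in the list of aromatic-ring oxygenases, and the lists were also tested without them, a choice made after the data were seen.

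Named genes followed a fixed rule, which took 48 genes. It took the 8 largest rises and 8 largest falls among genes past the threshold with no overlap between groups, a mean of at least 10 TPM in the higher group and an informative annotation. It added up to 4 tetracycline resistance genes by smallest p, 2 genes of each list past the threshold or fitting the treatment, and the 3 most abundant changed genes. The 2 genes of a list were those with the largest absolute change. Calls and changes in this rule were on TPM without scaling, where most genes were higher, so it favours risers. Genes named outside it were chosen after their values were seen, and the text says where. Runs of 5 or more neighbouring genes called in one direction were counted in order of the authors' gene numbers, and 10000 permutations of the calls gave the number expected by chance. Coordinates and strand were not used, so runs may cross contig ends or strands.

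On simulated data, with 3559 genes in the fit for tetracycline against control, 40% of genes changed by 1 log2 unit and 87% of those changed by 2 were recovered. Of unchanged genes, 0.0901% were called. The simulation changed 100 genes at each size and a list of 30, with no shift of the median gene. The genes changed at these 2 sizes were drawn from those above the lowest control values. These rates need not hold in the real fit, where 2766 genes were called on TPM. Alternatives covered scaling, low-value filter, pseudocount, replicate block, list test and each library left out. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.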

Results

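The transcriptome of Sphingobacterium sp. WM1 was measured in 3 control libraries without tetracycline and 3 libraries from cultures with tetracycline at 50 mg/L. Tetracycline is an antibiotic that binds the small ribosomal subunit and blocks translation. The series title places the comparison in the degradation of tetracycline by this strain. Expression was given as TPM and the sequencing depth is unknown. Growth phase and time of harvest are not given in the sources used here, so a difference in growth stage between the groups is not separated from tetracycline. Libraries of one group correlated at a Pearson r of 0.950 to 0.978 on log2(TPM + 1) across genes, and libraries of different groups at 0.769 to 0.792. The first principal component, computed after median-ratio scaling, carried 79.1% of the variance and separated the groups.

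1 row, sRNA0066, took 60.6% ± 4.96 (SD, n = 3) of all TPM in the control libraries and 26.8% ± 5.30 (SD, n = 3) in the tetracycline libraries. All sRNA rows together took 65.7% ± 4.11 and 29.3% ± 6.06, and annotated genes took 28.8% ± 3.25 and 66.2% ± 8.74 (SD, n = 3 each). The median gene stood 1.37 log2 units higher with tetracycline on the TPM scale. Changes given as scaled are relative to the typical gene. The sRNA0066 change was -1.19 ± 0.42 on TPM (SE, limma adjusted p = 0.0184) and -2.76 ± 0.52 after scaling (adjusted p = 0.00239). On TPM it missed the threshold without control replicate 1 (change -1.20, adjusted p = 0.0769) or without control replicate 3 (change -1.13, adjusted p = 0.0567). Whether sRNA0066 is ribosomal RNA, another structural RNA or a product of quantification was not settled here, so the meaning of these shares and of the 1.37 shift stays open.

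**Figure D1:**
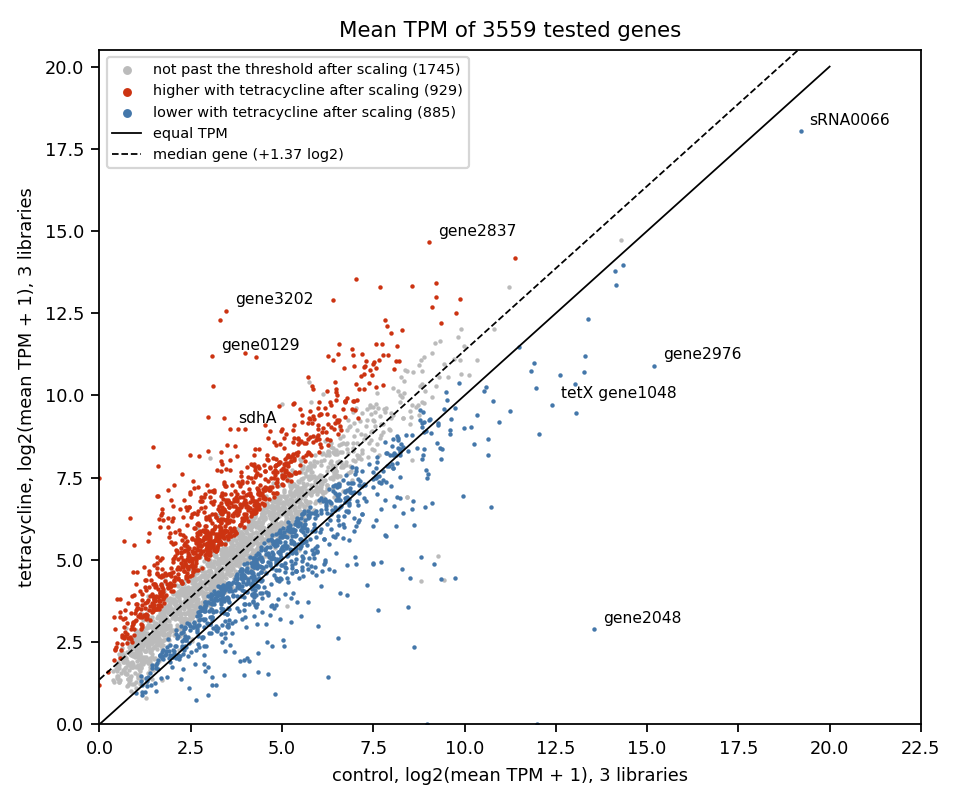
Mean TPM of 3559 tested genes in 3 control libraries (x axis) and 3 tetracycline libraries (y axis), both as log2(mean TPM + 1). Points are genes, red if higher and blue if lower after scaling at adjusted p 0.05, grey otherwise; the dashed line lies 1.37 log2 units above the line of equal TPM, and sRNA0066 and gene2976 lie below both lines.

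Tetracycline against control asked which genes differ when the strain grows with the antibiotic. Among genes with an informative annotation, the 8 largest rises included an outer membrane beta-barrel protein, a TonB-dependent receptor, a SusD lipoprotein and a sigma factor, and the 8 largest falls included genes of a phage tail-like locus. gene3202, an outer membrane beta-barrel protein, rose from 10.1 ± 4.48 to 6058 ± 1532 TPM (mean ± SD, n = 3 each), a log2 change of 9.13 on TPM and 7.63 ± 0.28 (SE) after scaling. gene2048, a phage tail protein, fell from 11902 ± 3879 to 6.40 ± 1.15 TPM (mean ± SD, n = 3 each), a log2 change of -10.62 on TPM and -12.04 ± 0.30 (SE) after scaling. Both had every library of one group beyond every library of the other.

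On TPM, 2766 of 3559 genes changed, 2609 higher and 157 lower, and 2380 of them by 2-fold or more. After scaling, 1814 genes changed, 929 higher and 885 lower, and 1270 of them by 2-fold or more. Higher genes thus made up 94.3% of the calls on TPM and 51.2% after scaling. Of the scaled calls, 1242 were also called on TPM, 1086 of them in the same direction.

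Other genes with the largest rises included gene0129, a TonB-dependent receptor (scaled log2 change 6.60 ± 0.28), the sigma factor gene3200 (5.89 ± 0.34) and susD gene3165, a nutrient-binding outer membrane lipoprotein (5.68 ± 0.22). The PEGA domain gene1558 rose by 5.56 ± 0.59, and the neighbouring DUF4252 genes gene2835 and gene2834 rose by 4.90 ± 0.35 and 4.86 ± 0.36 (scaled, SE). On TPM these changes were 8.09, 7.41, 7.17, 7.08, 6.46 and 6.43, and that of gene1558 ran from 6.69 to 7.75 without 1 library. catB gene1051, a chloramphenicol acetyltransferase, was listed at 0 in each of the 3 control libraries and had 180 ± 66.5 TPM (SD, n = 3) with tetracycline. Other catB rows exist in the table, so division of reads among copies leaves its level uncertain.

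Beside gene2048, its neighbours gene2049 (phage tail protein, scaled log2 change -7.57 ± 0.32) and gene2047 (DUF5908, -6.46 ± 0.40) fell. The DoxX family gene2556 fell by 6.45 ± 0.33 after scaling, from 657 ± 199 to 20.4 ± 6.69 TPM (SD, n = 3 each). novel0014, similar to the cytochrome oxidase accessory protein CcoG, changed by -5.08 ± 0.46, and novel0037, similar to the conjugal transfer protein TraG, by -4.50 ± 0.43. The Ig-like domain gene1870 changed by -4.32 ± 0.22 and the aminoglycoside phosphotransferase gene1044 by -4.30 ± 0.24 (scaled, SE). The hypothetical gene2976 fell from 37558 ± 6876 to 1913 ± 396 TPM (SD, n = 3 each), with a scaled change of -5.87 ± 0.41. All of these falls also passed on TPM, where changes ran from -6.19 for gene2049 to -2.77 for gene1044.

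**Figure D2:**
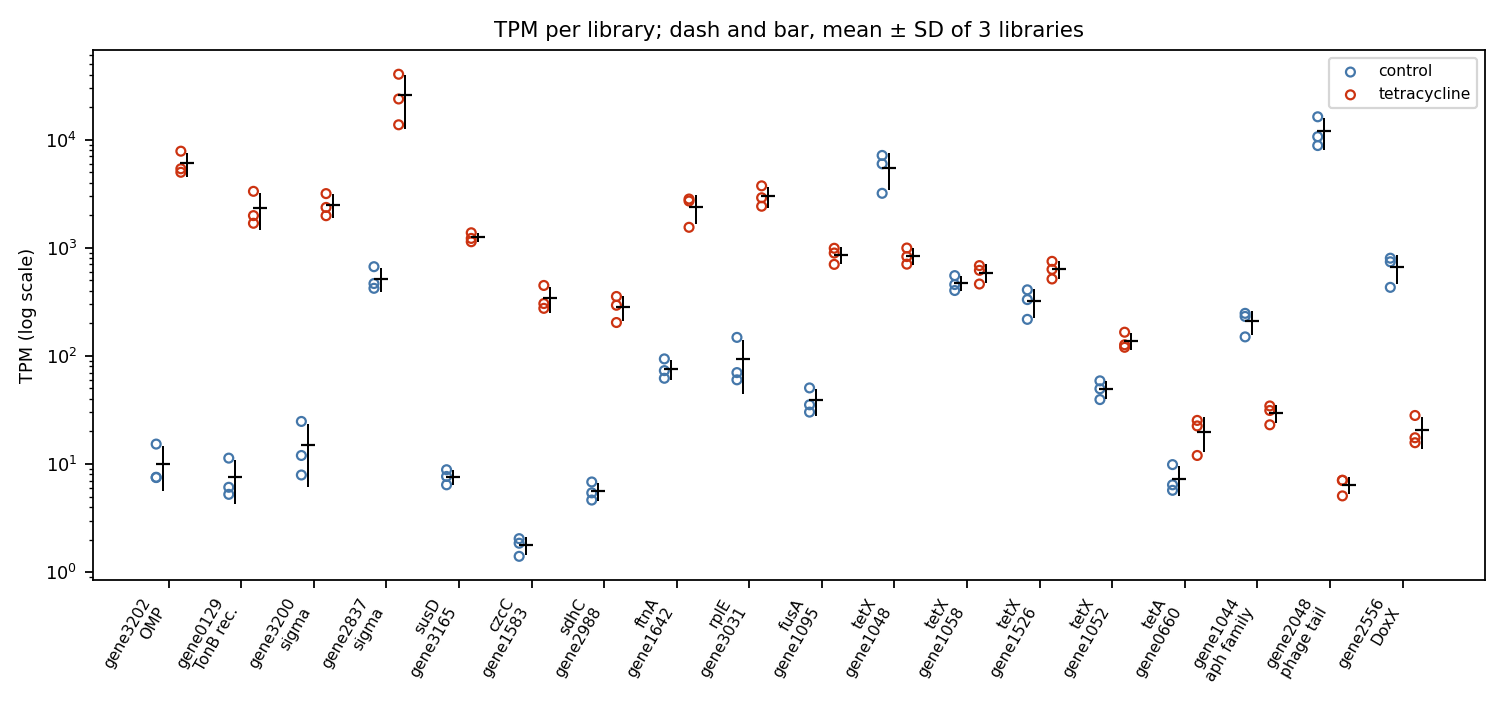
TPM per library (log axis) of 18 genes in 3 control (blue circles) and 3 tetracycline (red circles) libraries; dashes with vertical bars are the mean ± SD. gene3202 and gene2837 were far higher and gene2048 far lower with tetracycline, while tetX gene1048 was lower and tetX gene1052 was higher on the TPM scale shown.

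Of 5 tetracycline resistance genes, 4 were rows with the symbol tetX, a flavin-dependent monooxygenase that inactivates tetracyclines. The description of gene1048 is only FAD binding domain protein, so its identity as tetX rests on the symbol, while the other 3 are described as TetX or Tet(X). On TPM, 3 members rose, 1 fell and 1 did not pass; after scaling, 0 rose, 2 fell and 3 did not pass, and adjusted over the list alone the counts were the same on both scales. The most abundant row, tetX gene1048, fell from 5432 ± 2031 to 842 ± 145 TPM (SD, n = 3 each), a log2 change of -2.62 ± 0.39 on TPM and -4.19 ± 0.37 after scaling (SE, adjusted p = 5.54e-05). tetX gene1052 had 49.3 ± 9.67 and 137 ± 24.6 TPM, a change of 1.46 on TPM but -0.09 after scaling (adjusted p = 0.767). The tetracycline efflux gene tetA (gene0660) went from 7.33 ± 2.23 to 19.9 ± 7.02 TPM, 1.30 on TPM but -0.15 after scaling (adjusted p = 0.633). tetX gene1526 changed by 1.01 on TPM and by -0.56 after scaling (adjusted p = 0.138), and on TPM it missed the threshold without control replicate 3 (adjusted p = 0.0661) or tetracycline replicate 2 (adjusted p = 0.0580). The remaining tetX row, gene1058, named after its values were seen, had 470 ± 76.0 and 588 ± 114 TPM, and fell only after scaling (-1.25 ± 0.26, adjusted p = 0.00419). As a list, the members were not past camera's threshold (adjusted p = 0.201 on TPM and 0.137 after scaling); its TPM median and mean were 1.01 and 0.29, yet camera's direction, against the other genes, was down. Reads shared among the tetX rows leave single rows uncertain.

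Most genes of the translation machinery rose. Of 58 tested genes of the ribosomal protein list, which also holds the modifying enzymes rimK, prmA and rimO, 56 rose and 1 fell on TPM, and 45 rose, 2 fell and 11 did not pass after scaling; adjusted over the list alone, the scaled counts were 45 and 2. Their median scaled log2 change was 1.72 (camera adjusted p = 0.000102 on TPM; adjusted p = 0.921 with an estimated correlation). rplE gene3031 rose from 92.8 ± 48.3 to 3018 ± 666 TPM and rpsE gene3026 from 51.8 ± 26.6 to 1501 ± 298 TPM (SD, n = 3 each), by 3.54 ± 0.40 and 3.37 ± 0.38 after scaling (SE). rpsJ gene1094, named after its values were seen, fell from 10164 ± 1340 to 2334 ± 423 TPM, a scaled change of -3.70 ± 0.40 and -2.13 on TPM. All 21 aminoacyl-tRNA synthetase genes, which charge transfer RNAs, rose on TPM, and 14 rose, 0 fell and 7 did not pass after scaling, also 14 adjusted over the list alone. The camera adjusted p was 0.00510 (adjusted p = 0.921 with an estimated correlation), and asnS gene0480 and leuS gene1843 rose by 2.02 ± 0.24 and 2.10 ± 0.24 after scaling (3.52 and 3.51 on TPM).

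Of 21 translation factor genes, 9 rose, 3 fell and 9 did not pass after scaling, also 9 and 3 adjusted over the list alone, and 18 rose on TPM (camera adjusted p = 0.122). fusA gene1095, elongation factor G, rose from 38.7 ± 10.6 to 861 ± 146 TPM, and yhbH gene1640, a ribosome-associated translation inhibitor, from 214 ± 109 to 3042 ± 1431 TPM (SD, n = 3 each). Their scaled changes were 2.91 ± 0.26 and 2.28 ± 0.43 (SE). Of 11 RNA polymerase genes, 3 rose, 2 fell and 6 did not pass after scaling, also 3 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.314).

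Genes of energy metabolism also rose more often than they fell. All 18 genes of the citric acid cycle list rose on TPM, and 11 rose, 0 fell and 7 did not pass after scaling, with 11 adjusted over the list alone (camera adjusted p = 0.00286; adjusted p = 0.921 with an estimated correlation). The succinate dehydrogenase genes sdhC gene2988 and sdhA gene2989 rose from 5.62 ± 1.11 to 284 ± 75.9 TPM and from 10.9 ± 0.416 to 502 ± 98.9 TPM (SD, n = 3 each), by 3.93 ± 0.25 and 3.87 ± 0.22 after scaling. 1 riser in this list, leuB gene2933, is a leucine synthesis gene. Of 48 respiration and ATP synthase genes, 40 rose and 2 fell on TPM, and 27 rose, 8 fell and 13 did not pass after scaling, with 30 and 8 adjusted over the list alone. This list missed camera's threshold on TPM (adjusted p = 0.0806) and passed it after scaling (adjusted p = 0.00882; adjusted p = 0.530 with an estimated correlation). On TPM it also passed without control replicate 3 (adjusted p = 0.0238) or tetracycline replicate 3 (adjusted p = 0.0164). Of 15 glycolysis and gluconeogenesis genes, 10 rose, 3 fell and 2 did not pass after scaling, also 10 and 3 adjusted over the list alone. Their camera adjusted p was 0.120 on TPM and 0.0472 after scaling (adjusted p = 0.484 with an estimated correlation). They did not pass with upper-quartile scaling or with TPM over annotated genes only.

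In each biosynthetic list, more genes rose than fell. Of 62 amino acid synthesis genes, 57 rose and 1 fell on TPM, and 29 rose, 6 fell and 27 did not pass after scaling, with 30 and 6 adjusted over the list alone (camera adjusted p = 0.00286; adjusted p = 0.921 with an estimated correlation). lysC gene1967, aspartate kinase, rose by 2.39 ± 0.26 and argE gene3010 by 2.37 ± 0.22 after scaling (3.77 and 3.81 on TPM). Of 37 nucleotide synthesis genes, 34 rose on TPM, and 19 rose, 5 fell and 13 did not pass after scaling, also 19 and 5 adjusted over the list alone. Its camera adjusted p was 0.0214 (adjusted p = 0.921 with an estimated correlation), and 0.0522 without tetracycline replicate 1. The pyrimidine synthesis genes pyrC gene1368 and pyrD gene2380 rose by 2.25 ± 0.19 and 2.14 ± 0.19 after scaling (3.75 and 3.55 on TPM). Of 38 cell wall and envelope synthesis genes, 37 rose on TPM, and 13 rose, 7 fell and 18 did not pass after scaling, with 13 and 8 adjusted over the list alone. murC gene2777 of peptidoglycan synthesis rose by 1.95 ± 0.25 and the deacetylase gene2385 by 2.62 ± 0.35 after scaling (3.49 and 4.15 on TPM). This list's camera adjusted p was 0.0475 (adjusted p = 0.921 with an estimated correlation) and 0.199 after scaling. It missed the threshold in 5 of the 6 fits without 1 library, with adjusted p of 0.0511 and 0.0592 without control replicates 1 and 3 and 0.0522, 0.0717 and 0.0636 without tetracycline replicates 1, 2 and 3, and also without 2 members of other function (adjusted p = 0.0575). Of 16 fatty acid synthesis genes, 6 rose, 4 fell and 6 did not pass after scaling, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.437).

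**Figure D3:**
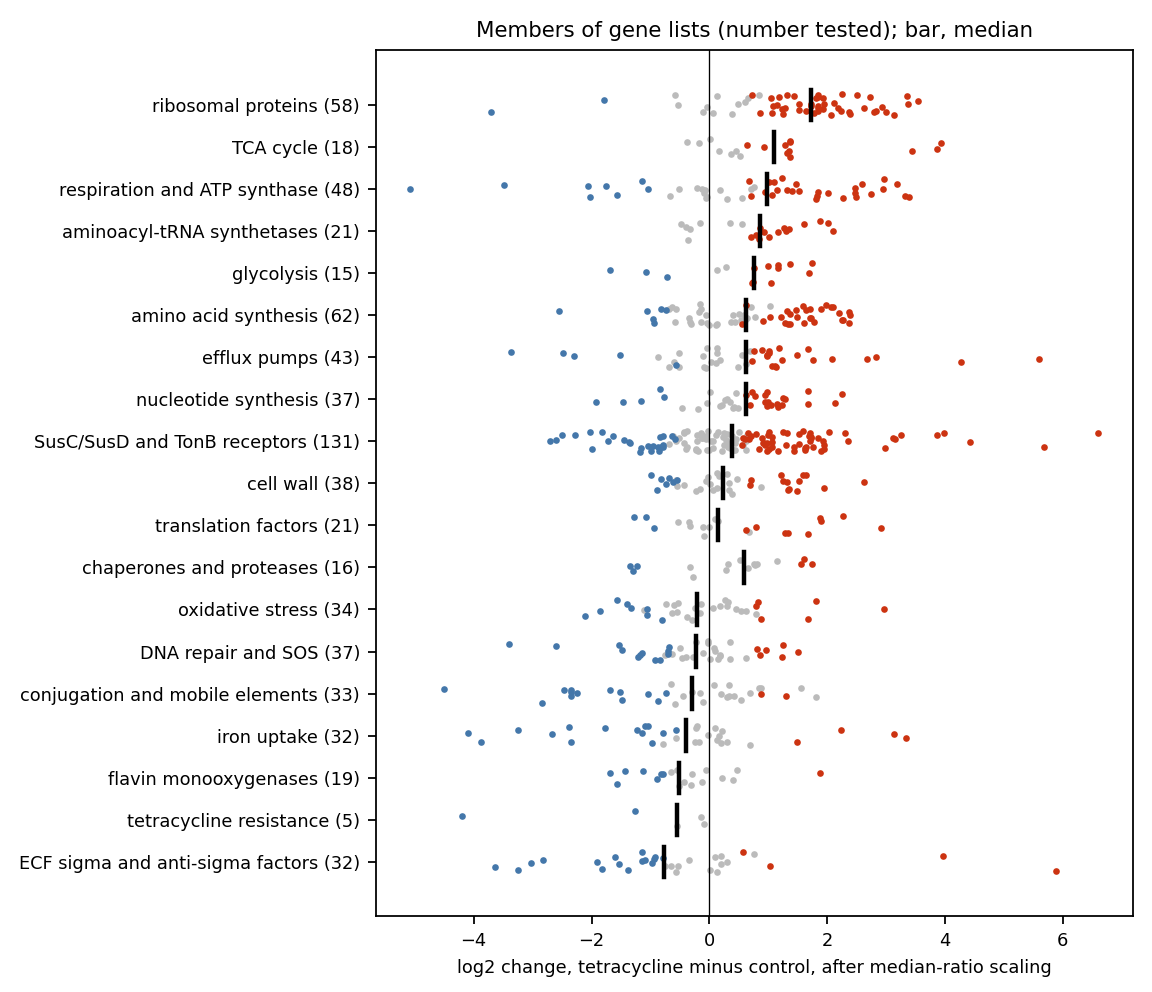
Log2 change after scaling (x axis, tetracycline minus control) of each tested member of 19 gene lists (rows, with the number tested); points are genes, red if higher and blue if lower at adjusted p 0.05, grey otherwise, with vertical jitter for legibility, and black bars are medians. The ribosomal protein list has the highest median (1.72) and the list of sigma and anti-sigma factors the lowest (-0.77); on TPM without scaling the median gene lies 1.37 higher.

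Among efflux pump genes, czcC gene1583 and czcA gene1585, components of a heavy metal efflux pump, rose from 1.76 ± 0.329 to 343 ± 92.5 TPM and from 4.58 ± 1.02 to 291 ± 35.8 TPM (SD, n = 3 each), by 5.60 ± 0.20 and 4.27 ± 0.24 after scaling. Of 43 efflux genes, 37 rose and 3 fell on TPM, and 20 rose, 5 fell and 18 did not pass after scaling, also 20 and 5 adjusted over the list alone. The list's camera adjusted p was 0.314 on TPM and 0.0331 after scaling (adjusted p = 0.484 with an estimated correlation). The list passed camera under no scaling other than the median-ratio one. Of 131 SusC, SusD and TonB-dependent receptor genes, which take up glycans and other nutrients, 55 rose, 26 fell and 50 did not pass after scaling, with 55 and 27 adjusted over the list alone. Their camera adjusted p was 0.395 on TPM and 0.0297 after scaling (adjusted p = 0.484 with an estimated correlation). They did not pass with median-centring or with TPM over annotated genes only. Major facilitator transporters (28 genes; 11 rose, 5 fell), ABC transporters (48 genes; 9 rose, 10 fell) and gliding or type IX secretion genes (6 genes; 1 rose, 0 fell) did not pass on either scale. Their camera adjusted p on TPM was 0.395, 0.589 and 0.488, and adjusted over the list alone the scaled counts were 11 and 5, 7 and 9, and 1 and 0.

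Iron genes divided. Ferritin ftnA gene1642 rose from 76.3 ± 16.1 to 2356 ± 705 TPM and tonB gene3458, which energizes outer membrane receptors, from 92.4 ± 13.4 to 2432 ± 271 TPM (SD, n = 3 each), by 3.34 ± 0.30 and 3.14 ± 0.27 after scaling. Another tonB row, gene0497, named after its values were seen, fell from 145 ± 16.2 to 83.2 ± 11.2 TPM (SD, n = 3 each). Its change was -0.80 on TPM (limma adjusted p = 0.0142) and -2.36 ± 0.24 after scaling. Of 32 iron uptake and storage genes, 16 rose and 4 fell on TPM, and 4 rose, 14 fell and 14 did not pass after scaling, also 4 and 14 adjusted over the list alone. As a list they lay below the other genes (camera adjusted p = 0.0214; adjusted p = 0.921 with an estimated correlation), although their median on TPM was 1.03. The camera adjusted p was 0.138 after scaling and 0.0522 on TPM without tetracycline replicate 1.

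The list of extracytoplasmic function sigma factors and anti-sigma factors, regulators that respond to signals at the cell envelope, lay lower than other genes apart from a few strong risers. It also holds rpoD gene2001, which is not an extracytoplasmic function sigma factor. That gene, named after its values were seen, is among the scaled falls (-0.92 ± 0.28, adjusted p = 0.0226). The sigma factor gene2837 rose from 519 ± 131 to 25895 ± 13386 TPM (SD, n = 3 each), 5.53 on TPM and 3.96 ± 0.43 after scaling. Of 32 members, 13 rose and 4 fell on TPM, and 4 rose, 16 fell and 12 did not pass after scaling, with 5 and 17 adjusted over the list alone. The median was 0.48 on TPM and -0.77 after scaling (camera adjusted p = 0.00286, direction down; adjusted p = 0.921 with an estimated correlation). With symbol matches alone the list missed camera's threshold (adjusted p = 0.0625), although the difference from other genes was larger (-0.96 against -0.64). Of 33 conjugation and mobile element genes, 17 rose and 6 fell on TPM, and 2 rose, 13 fell and 18 did not pass after scaling, also 2 and 13 adjusted over the list alone. Their median was 0.78 on TPM and -0.29 after scaling, with a camera adjusted p of 0.00286, direction down (adjusted p = 0.921 with an estimated correlation), and 0.0949 after scaling. Among them, the transposase gene3584 changed by 3.02 ± 0.96 on TPM (adjusted p = 0.0359) and 1.81 ± 1.04 after scaling (adjusted p = 0.201). Its TPM call was lost without control replicate 3 (adjusted p = 0.0828) or without tetracycline replicate 1, 2 or 3 (adjusted p = 0.0619, 0.0548 and 0.111), and its TPM change ran from 2.04 to 3.66 without 1 library.

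Stress lists did not pass the list test on either scale. Of 34 oxidative stress genes, 6 rose, 8 fell and 20 did not pass after scaling (camera adjusted p = 0.986 on TPM), with 5 and 8 adjusted over the list alone. The thioredoxin family gene0190 rose by 2.96 ± 0.23 and the cytochrome-c peroxidase gene1571 by 1.81 ± 0.27 after scaling (4.47 and 3.29 on TPM). Other genes, named after their values were seen, fell after scaling: superoxide dismutase gene2983 (-1.32 ± 0.25), katG gene1994 (-1.07 ± 0.25), katE gene3559 (-1.85 ± 0.54) and oxyR gene1929 (-1.06 ± 0.33). On TPM these did not pass (limma adjusted p = 0.484, 0.138, 0.653 and 0.223). Of 16 chaperone and protease genes, 3 rose, 3 fell and 10 did not pass after scaling, also 3 and 3 adjusted over the list alone, and the camera adjusted p was 0.431. The risers included trigger factor tig gene2814 (1.74 ± 0.25 scaled, 3.24 on TPM) and the Hsp20 family gene2197 (1.61 ± 0.20 scaled, 3.14 on TPM). The chaperone gene dnaJ gene1913, named after its values were seen, fell after scaling (-1.35 ± 0.28, adjusted p = 0.00388). On TPM it changed by 0.22 without passing (limma adjusted p = 0.520). Of 37 DNA repair and SOS genes, 6 rose and 12 fell after scaling, also 6 and 12 adjusted over the list alone (camera adjusted p = 0.652). Of 19 flavin monooxygenase and oxidoreductase genes, 1 rose, 7 fell and 11 did not pass after scaling, also 1 and 7 adjusted over the list alone (camera adjusted p = 0.437). gene1537, an FAD-binding oxidoreductase, rose by 1.88 ± 0.19 after scaling and 3.33 on TPM, while sqr gene1704 changed by 1.88 ± 0.31 on TPM and 0.41 ± 0.29 after scaling (adjusted p = 0.274). Of 19 aromatic-ring oxygenase list members, 6 rose and 5 fell after scaling, also 6 and 5 adjusted over the list alone (camera adjusted p = 0.652), and the members with the largest rise, catB genes, are chloramphenicol acetyltransferases.

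Genes that neighbour each other in gene number moved together. After scaling, 21 runs of 5 or more genes were all higher and 14 all lower, against permutation means of 2.89 and 1.82 runs (permutation p = 0.0001 each, the smallest that 10000 permutations can give). The longest higher run, gene3023 to gene3042, held 20 genes, secY and ribosomal protein genes, with a median log2 change of 2.49. The next, gene3010 to gene3021, held 12 genes, including argE, argB, rpoA and infA (median 1.52). Runs of 11 genes were gene2583 to gene2593, with SusC and SusD genes (median 1.54), and gene3441 to gene3451, nuoN to nuoD of NADH-quinone oxidoreductase (median 2.59). The longest lower run, gene2038 to gene2056, held 19 genes, among them phage tail, PAAR domain and VgrG genes, with a median of -3.04. The next, gene0255 to gene0264, held 10 genes from maleate isomerase nicE to a cyclase, including an FAD-dependent monooxygenase (median -1.24). 3 runs of 8 genes followed, gene1297 to gene1304, gene1809 to gene1816 and gene2853 to gene2860, with medians of -1.59, -3.89 and -1.21. On TPM, where most genes were higher, 205 higher runs compared with a permutation mean of 194 (permutation p = 0.0835), and the 1 lower run, gene2038 to gene2054 with 17 genes, compared with a mean of 0.0004 (permutation p = 0.0005).

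**Figure D4:**
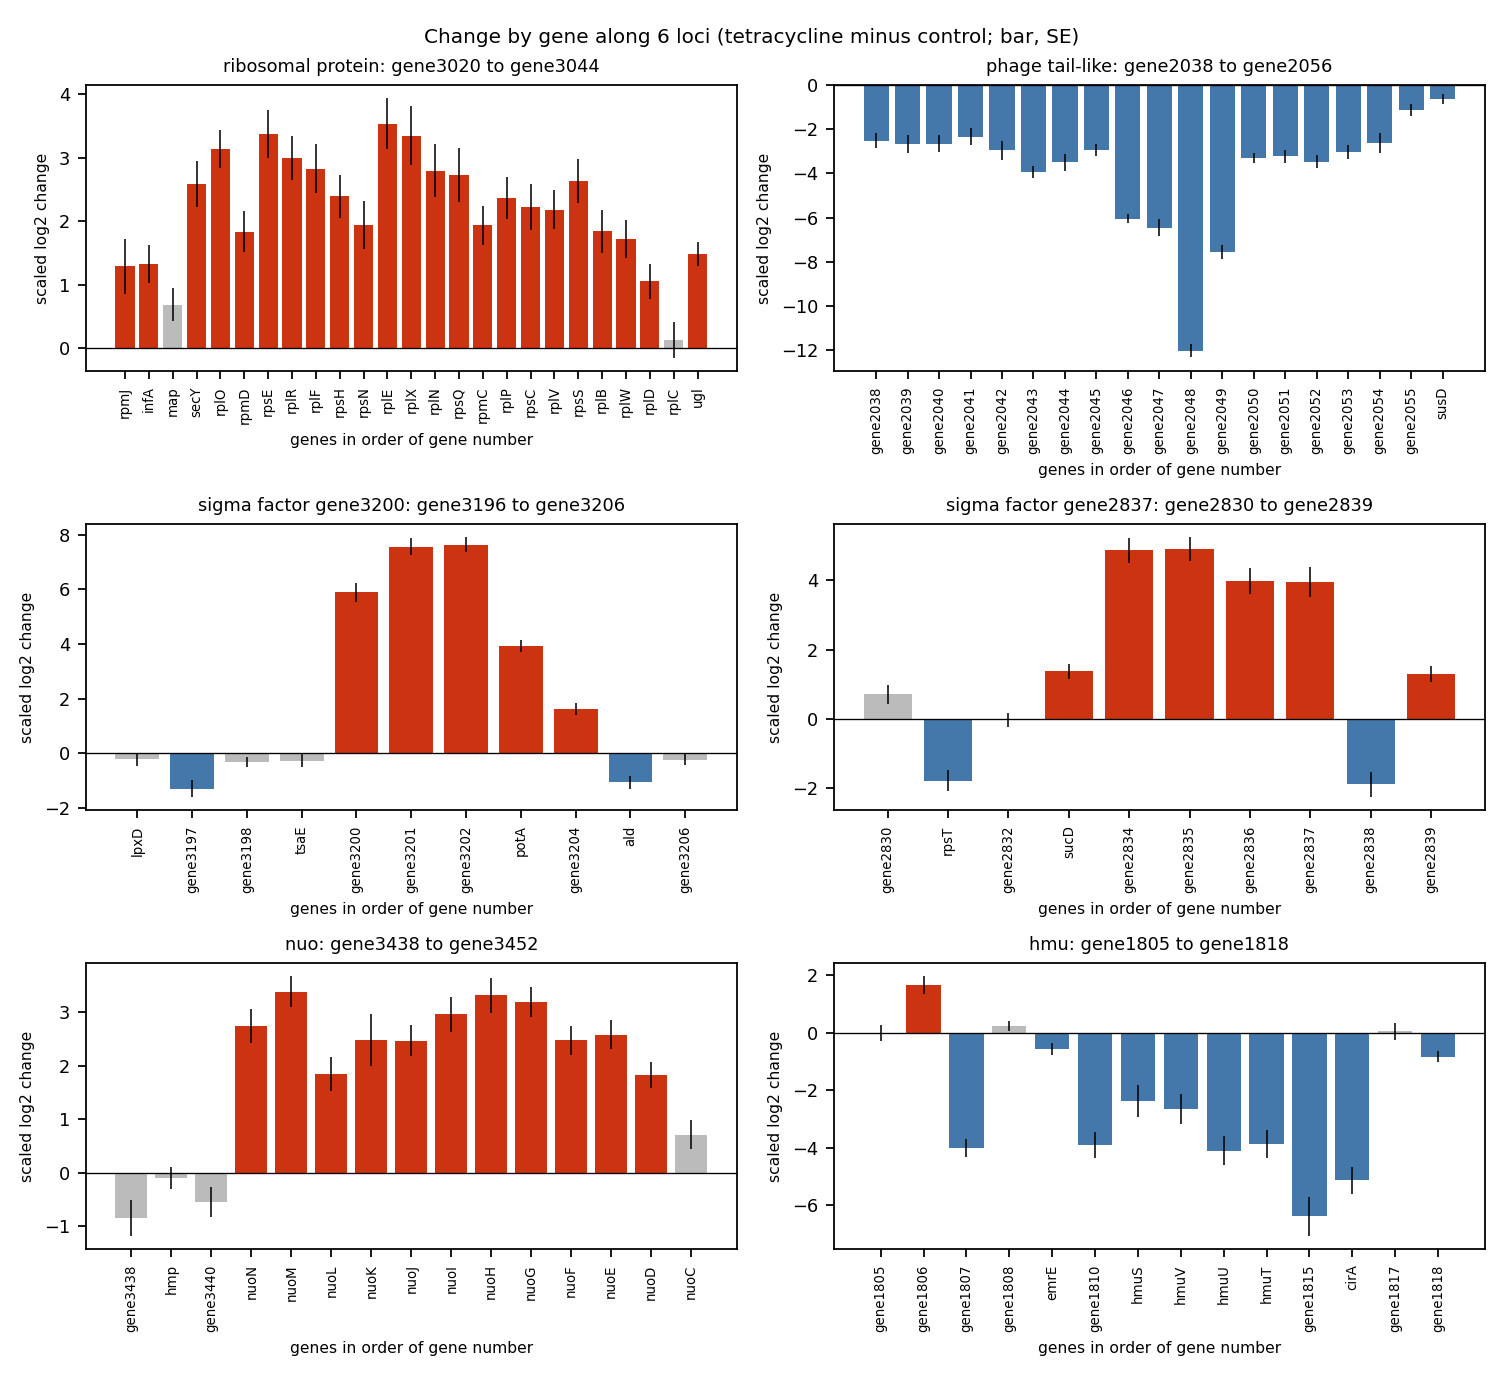
Log2 change after scaling (y axis, tetracycline minus control; error bars, SE) of neighbouring genes (x axis, in order of gene number) at 6 loci; bars are red if higher and blue if lower at adjusted p 0.05, grey otherwise. The phage tail-like locus reaches -12.04 at gene2048, and gene3202 beside the sigma factor gene3200 reaches 7.63.

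The authors' deposited table called 1342 genes, 698 higher and 644 lower with tetracycline, all with an adjusted p of at most 0.00992 and an absolute log2 fold change of at least 1. Of these, 1336 were among the genes tested here, and 1325 passed in the same direction after scaling, against 852 on TPM. The authors' log2 fold changes had a median of -0.01 over the tested genes, so they too are relative to the typical gene. They come from the same 6 libraries, and their limits were stricter, so this match is not independent support for the scaled calls. The log2 ratio of mean TPM exceeded the log2 fold change of the authors' deposited table by 1.57 (median of 2527 genes, SD 0.05 across genes). 2 tested rows were listed at 0 in every control library and 2 in every tetracycline library. With the preset correlation, the 6 lists past camera's threshold on both scales were ribosomal proteins, aminoacyl-tRNA synthetases, citric acid cycle, amino acid synthesis, nucleotide synthesis and sigma factors; with an estimated correlation, 0 lists passed on either scale.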

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

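Median-centring, TPM renormalized over annotated genes, scaling combined with another choice, runs under other gene tests and lists without members of other function were chosen after the data were seen. Scaling moved the counts of genes and runs, by construction, since it removes the shift of the median gene. Against 2766 genes on TPM (2609 higher, 157 lower), median-ratio scaling gave 1814 (929 and 885), upper-quartile scaling 1795 (934 and 861), median-centring 1672 (913 and 759) and TPM over annotated genes only 1777 (1254 and 523). Runs of neighbouring genes, 206 on TPM in both directions, numbered 35, 34, 34 and 45 under the same settings. After scaling, runs of 4 or more genes numbered 44 higher and 24 lower, and lower runs of 6 or more numbered 8, against 21 and 14 of 5 or more; the length limit sets these. For lists, 9 passed camera, 0 of 25 with an estimated correlation (0 also at an unadjusted p under 0.05) and 23 with fry. Fry tests a list against no change, and after scaling, which removes the shift of the median gene, 20 lists passed it. tetX gene1052 reversed to -0.087 under median-ratio and -0.060 under upper-quartile scaling. tetA gene0660 reversed to -0.15, -0.12 and, median-centred, -0.069. tetX gene1526 reversed to -0.56, -0.53, -0.35 median-centred and -0.18 over annotated genes. The oxidative stress list, -0.01 against other genes, reversed to 0.026 without a filter, 0.11 with a pseudocount of 5 and 0.077 without control replicate 2 (range -0.069 to 0.077 without 1 library); the cause was not tested. Without 1 library in turn, 2562 to 2803 genes changed, 2408 to 2679 higher and 124 to 160 lower. After scaling, 745 to 926 were higher and 719 to 848 lower. Lists numbered 6 to 9, runs 191 to 211, and scaled runs 15 to 21 higher and 10 to 13 lower. Of 288 values of 48 named genes without 1 library, 280 kept their side of the threshold and 8 lost it, and of 429 under other settings, 407 kept it, 13 lost it and 9 reversed. Of 150 values of 25 lists without 1 library, 140 kept their side, 7 lost it, 2 gained it and 1 reversed, and of 320 under other settings the numbers were 265, 26, 27 and 2. A filter at 5 TPM ended the list calls of cell wall, iron uptake and nucleotide synthesis (adjusted p = 0.0949, 0.0580 and 0.0580), with differences from other genes of 0.39, -0.54 and 0.53 against 0.46, -0.57 and 0.61, and symbol matches alone ended that of sigma factors (adjusted p = 0.0625), with a larger difference from other genes (-0.96 against -0.64). Without members of other function 8 lists passed, and cell wall did not. Testing against a 1.5-fold change left 2048 genes.

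The replicate block, with the replicate number as a term, gave 2678 genes and 10 lists, and the list of translation factors passed (adjusted p = 0.0490; adjusted p = 0.921 with an estimated correlation and no block) while gene3584 did not (adjusted p = 0.0722). The numbers do not pair the samples: same-numbered libraries deviated with correlations of -0.169, 0.0422 and -0.0910, and only replicate 2 matched its own number best. Count-based alternatives (DESeq2, limma-voom, count filters) were not run because the values are TPM, library size alone equals the main setting, and runs on 1 strand were not run because no strand was used. Depth is unknown, so the precision of low values cannot be stated.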

Other observations

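The tests in this part, including the pathway and row-class tests and the counts of other splits, were chosen after the results were seen, except the list tests, which were planned. The genes named here were also chosen then, except tetX gene1048, gene3200, gene2837, czcC and czcA, which the fixed rule took. nuoM gene3442 and nuoH gene3447 of NADH-quinone oxidoreductase rose by 3.39 ± 0.29 and 3.32 ± 0.33 after scaling (SE). Further genes of this enzyme lie in gene0686 to gene0692, a run of 7 genes that also holds a DUF4254 gene. Scaled changes in that run had a median of 0.76 and ranged from -0.66 to 1.40. The cbb3-type oxidase genes ccoNO gene0993 and ccoP gene0995 rose by 3.21 ± 0.42 and 2.95 ± 0.37 after scaling (SE). A further cbb3-type oxidase gene, ccoN gene0804 (-2.03 ± 0.23), and cydB gene3185 of cytochrome d oxidase (-2.05 ± 0.22) fell after scaling, while on TPM they changed by -0.56 and -0.52 without passing (adjusted p = 0.0686 and 0.0842). The accessory protein gene gene0996 (CcoG), numbered next to ccoP gene0995, fell by 3.48 ± 0.32 after scaling and 1.91 on TPM, and ccoO gene0805 fell by 1.75 ± 0.36 after scaling only (TPM -0.46, adjusted p = 0.394). The heme uptake genes hmuT gene1814 and hmuU gene1813 fell from 179 ± 119 to 28.8 ± 3.32 TPM and from 110 ± 66.4 to 14.4 ± 2.26 TPM (SD, n = 3 each), by 3.88 ± 0.49 and 4.10 ± 0.50 after scaling. hmuV gene1812 and hmuS gene1811 of the same locus changed by -2.66 ± 0.52 and -2.38 ± 0.56 after scaling. On TPM these 2 genes changed by -1.25 and -0.93 without passing (limma adjusted p = 0.0525 and 0.172). feoB gene2611 for ferrous iron transport rose by 1.48 ± 0.25. The starch utilization genes susC gene3237 and susD gene3236 rose by 3.87 ± 0.30 and 3.98 ± 0.34. Between czcC and czcA, czcB gene1584 changed by -0.69 ± 0.28 after scaling (adjusted p = 0.0656) and by 0.88 on TPM. Among other resistance genes, cmlA gene1524, a florfenicol efflux gene, fell from 3828 ± 321 to 2042 ± 221 TPM (-2.48 ± 0.33 scaled), and catB gene0628 rose from 10.9 ± 1.99 to 213 ± 25.5 TPM (2.65 ± 0.20 scaled). Not all catB rows rose. catB gene1522 and gene1045 fell after scaling (-1.26 ± 0.32, adjusted p = 0.0101, and -1.04 ± 0.34, adjusted p = 0.0315). On TPM they changed by 0.12 and 0.45 without passing (adjusted p = 0.773 and 0.340).

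Of 106 pathways in the authors' annotation, 7 passed camera on TPM, all upward, with the smallest p for Ribosome (54 genes, adjusted p = 0.000496), the citric acid cycle (22 genes, adjusted p = 0.0144) and Carbon fixation pathways in prokaryotes (17 genes, adjusted p = 0.0156). 0 passed with an estimated correlation (adjusted p = 0.971 for each of these 3). Of 27 tested sRNA rows, 20 fell and 0 rose after scaling, and of 45 tested rows outside the annotation, 28 fell and 2 rose, against 837 falls among 3487 annotated genes (24.0%). Both shares differed from that of annotated genes (Fisher's exact test, adjusted p = 7.17e-08 each), with rows, which are not independent replicates, as units. On TPM, 14 of the 27 sRNA rows fell and 1 rose, and of the 45 rows outside the annotation 14 fell and 4 rose.

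The median gene's TPM stood 1.37 log2 units higher with tetracycline. Most of this shift went when TPM was renormalized over annotated genes alone, where the median change was 0.34. That median stayed between 0.272 and 0.410 without any 1 library, so the share taken by sRNA rows is not the whole cause. A rise common to all annotated genes would cancel in it. More messenger RNA per cell with tetracycline could also raise every gene, but without an external standard the value of 1.37 cannot be told apart from a change in the makeup of the total. A response to tetracycline stays open, untested.

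gene1048, tetX by its symbol alone, was lower with tetracycline while the other tetX rows were not all lower on TPM. Over 5 scalings, the highest of its log2 changes was -2.62, the unscaled TPM value. The other scalings remove some or all of an upward shift of the median gene, so they could only lower the change. The other scalings therefore add no test. On TPM itself, the median gene stood 1.37 higher with tetracycline while gene1048 changed by -2.62 ± 0.39 (SE). These values argue against the fixed total as the cause of its fall relative to the typical gene. Its level per cell is unknown without an external standard. Reads moved to the other tetX rows are argued against by the sum of the 4 rows, which changed by -3.03 ± 0.30 after scaling (SE), from 6271 ± 2206 to 2199 ± 346 TPM (SD, n = 3 each). Exchanged group labels stay open and cannot be told apart, since no gene had a response known in advance and of 5 tetracycline resistance genes 0 were higher and 2 lower after scaling, against 3 higher and 1 lower on TPM. A regulated response to tetracycline stays open, untested.

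Correlation between the genes of a list may account for part of the list calls. 0 lists passed with an estimated correlation, against 9 with the preset one. The 6 libraries make 10 splits, too few for a share under 0.1. Only the real split, 1 of the 10, reached 2766 genes on TPM (highest other 0), 1814 after scaling (highest other 1) or 9 lists (highest other 8). Each other split sets 2 libraries of one group and 1 of the other against the reverse, so it keeps part of the group difference, and its lists do not bear on correlation between genes.

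Sigma factor genes may move with their neighbours more than other genes do, a hypothesis from the loci of gene3200 and gene2837, so those 2 genes were left out of its test. Across the other 20 sigma factor genes, the scaled change and the mean of the 2 genes on each side had a Pearson r of 0.377 (permutation p = 0.101, adjusted 0.101). Spearman rho was 0.445 (permutation p = 0.0510, adjusted 0.101; 2 relations computed). This r lay at percentile 40.5 of 10000 random gene sets of the same size, whose median was 0.440 and 95th percentile 0.783. Without the 2 genes farthest from the median, r was 0.476, at percentile 55.4. No excess over other genes was seen, so these values give the hypothesis no support. With 20 genes the random sets spread too widely to exclude a small excess, so it is not excluded either. These correlations are across genes, which are not independent replicates.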
